A study of Mus musculus with 6 samples.

How the data were processed

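Poly-A RNA from mouse bone marrow-derived macrophages was sequenced from TruSeq libraries, per the labels' protocols, in 3 groups of 2 libraries: control, LPS, and LPS with HACA. Genes of the annotated type misc_RNA, which is not messenger RNA, held 24.3% to 29.2% of a library's counts. The counts were therefore not from messenger RNA alone, and the poly-A selection that the labels name was not checked. The submitters' processing notes name the builds GRCm38 and GRCh38 and the tools CASAVA, Trim Galore, STAR 2.5.4b, limma, edgeR 3.28.1 and DESeq2 1.26.0, with no role or order. The counting program and its handling of shared reads are not given in the sources used here. The authors deposited raw read counts per annotated transcript, per the file headers and the values, which were whole numbers with a different total in each library. They also deposited FPKM values, which equalled each count divided by transcript length and by one effective library size per library, to within 0.1% for 99.6% of transcripts with at least 50 counts.

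The planned unit was the gene, but the deposited counts were per transcript, so counts were summed per gene with the GENCODE annotation of GRCm38. Of 142647 transcripts, 141524 matched the annotation and fell into 55263 genes. The 1123 unmatched transcripts held at most 0.115% of a library's counts and stayed out of library sizes and tests. Transcripts with at least 100 bases shared with no other transcript held 99.2% of the counts, and transcripts with no base of their own held 0.057%. Reads overlapping several transcripts were therefore mostly missing from the counts, and genes with many overlapping isoforms were measured over a small part of their exons: 10.8% of exonic bases for Tnf, 6.6% for Il12b, 6.4% for Serpinb2, 2.6% for Nlrp3, 8.6% for Cnr2, 7.1% for Itgam, 9.4% for Pltp, 5.1% for Nlrp1b and 22.6% for Cd44. For these genes a change in isoform use cannot be separated from a change in expression. Reads that matched near-identical copies were counted at each copy, as for the 7SL RNA genes Rn7s1 and Rn7s2. Copies were searched only among genes with at least 1000 counts summed over the libraries, and no named gene in that set had one. Named genes with fewer counts, such as Csf2, were not searched.

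Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and one edgeR 4.0.16 quasi-likelihood model with robust dispersion was fitted to all 6 libraries in R 4.3.3. The model had the group as its only term and 3 residual degrees of freedom, and 17113 genes were tested. The 3 contrasts were LPS against control, LPS+HACA against LPS, and LPS+HACA against control. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Values are TMM-scaled CPM (library-scaled counts, as edgeR gives them), given as mean ± SD over 2 libraries, and log2 fold changes are given ± SE. This SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F. For genes with few counts in a group it can be smaller than the counting error. Where a group had 0 counts, the fold is a lower bound computed against 3 counts over the group. Where it had 1 to 3 counts, the ratio of summed counts is given with an exact 95% interval. Intervals and bounds cover counting error only. Tested on simulated counts with 200 changed genes, the same procedure recovered 49% of 4-fold and 1% of 2-fold changes for LPS against control (16472 genes), and 62% of 4-fold and 5% of 2-fold changes for LPS+HACA against LPS (16528 genes). It made 12 false calls in each and no call in the wrong direction. In these simulated sets the share of false calls among all calls was therefore above the 0.05 set by the adjusted p. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which can be technical.

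Before the data were examined, the groups, the model, the alternatives, the gene lists and the rule for named genes were fixed. That rule takes, in each of the first 2 contrasts, the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 5 in the higher group and no overlap between the libraries. It adds up to 2 members per direction of each list and 20 focus genes. The lists covered proinflammatory cytokines, chemokines, interferon-stimulated genes, NF-kB feedback regulators, TLR4 signalling parts, classical and alternative activation markers, hyaluronan receptors and enzymes, psoriasis-linked myeloid mediators, glycolysis, oxidative phosphorylation, cholesterol synthesis, LXR targets, NRF2 targets, lysosome and phagocytosis, MHC class I and II, the inflammasome, the cell cycle, the unfolded protein response and matrix remodelling. Further lists held markers of macrophages, dendritic cells, neutrophils, T and NK cells, B and plasma cells, stromal cells, mast cells, erythroid and megakaryocyte cells and keratinocytes, and immediate early and heat shock genes. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with the correlation between genes preset at 0.01, then with an estimated correlation, and with fry. Pathway lists were adjusted together.

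The LPS libraries enter both of the first 2 contrasts with opposite signs, so 100 simulations of an unchanged LPS+HACA group gave the overlap and correlation that arise with no effect. The same simulations with libraries scaled by their totals were added after seeing the data. Alternatives were DESeq2 size factors, library totals, 2 other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1), the replicate number as a block, a 2-fold minimum, fits of 4 libraries, and leaving out each library in turn. Protein-coding genes only, genes with 1 annotated transcript only, and transcripts tested one by one were added after seeing the data. Other tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The focus gene Ccl2 did not pass the filter on low counts. The comparisons give part of the genes that the naming rule selects, and the others are not reported here.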

Results

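Expression was measured in wild-type mouse bone marrow-derived macrophages, cells grown from marrow progenitors, in 3 groups of 2 libraries each. The groups were a control, cells given lipopolysaccharide (LPS), a bacterial membrane component sensed by TLR4, and cells given LPS together with a preparation labelled HACA. The labels do not spell out HACA and give no dose or time, and the series title is about a hyaluronic acid nanomedicine for psoriasis. Total counts were 13806911 and 13036776 in the control libraries, 12529874 and 15379496 in the LPS libraries, and 13933604 and 13007575 in the LPS+HACA libraries. At least 10 counts were found for 16507 and 16241 genes in control, 14006 and 13883 in LPS, and 16642 and 15973 in LPS+HACA. The replicate libraries correlated at r = 0.972, 0.951 and 0.961 across genes, and their counts differed by more than sampling noise in each group (chi-square per degree of freedom 26.2, 64.5 and 38.9). The near-identical 7SL RNA genes Rn7s1 and Rn7s2, where the same reads were counted at each copy, held 9.65% and 9.66% of the counts of the first control library, and between 9.20% and 10.6% each in every library. Genes higher in LPS held 33.7% and 35.2% of the control counts, 54.8% and 57.8% of the LPS counts, and 39.6% and 42.7% of the LPS+HACA counts.

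The first comparison asked what LPS did to the macrophages. Ptgs2, which encodes the inducible cyclooxygenase, rose from 2.39 ± 0.454 to 7305 ± 599.9 CPM (SD, n = 2 per group), a log2 fold change of 11.57 ± 0.33 (SE, adjusted p = 8.89e-06). The cytokine gene Tnf rose from 9.88 ± 3.42 to 1522 ± 740.7 CPM (7.27 ± 0.50 on the log2 scale, adjusted p = 0.000159), and Nos2, the inducible nitric oxide synthase, rose from 0.256 ± 0.0815 to 80.97 ± 21.5 CPM (8.25 ± 0.49, adjusted p = 0.000106). All 30 measured interferon-stimulated genes and all 15 measured proinflammatory cytokine genes rose. In the other direction, the lipid-sensing receptor gene Trem2 fell from 166 ± 16.5 to 7.36 ± 1.15 CPM (−4.50 ± 0.26, adjusted p = 0.000105).

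Of 17113 genes, 2715 were higher and 2442 lower in LPS. The groups did not overlap for 66.7% of genes, where chance gives 33.3%. The largest rises included Il12b, the shared subunit of interleukins 12 and 23, which had no count in control and 44.7 ± 11.2 CPM in LPS, at least 463-fold higher. Also at 0 in control were Areg and Ereg, 2 ligands of the epidermal growth factor receptor, Csf2, which encodes GM-CSF, Gfi1, a transcriptional repressor, and Serpinb2, a plasminogen activator inhibitor. These were at least 154, 77.7, 134, 98.8 and 77.2-fold higher in LPS. Csf2 and Gfi1 did not pass with DESeq2 (adjusted p = 0.0925 and 0.11). Il6 had 2 counts in control and 1212 in LPS, a ratio of 917 (95% interval 253 to 7578). Ptgs2 lies on chromosome 1 (150100031 to 150108227, GRCm38) and Il12b on chromosome 11 (44400063 to 44414033). The largest falls included Ptgs1, the constitutive cyclooxygenase, with 170 counts in control and 1 in LPS (ratio of control to LPS 112, interval 19.9 to 4464). The ratio was 89.6 (24.6 to 743) for Slc7a15, 85.3 (23.4 to 708) for the adaptor subunit gene Ap1b1, and 57.5 (15.7 to 479) for the cannabinoid receptor gene Cnr2. It was 57.2 (15.6 to 476) for Fam117a and 52.9 (14.4 to 440.4) for the Polycomb gene Cbx8. Rab3il1 changed by −6.03 ± 0.42 and Zfyve28, whose product binds endosomes, by −5.72 ± 0.31 on the log2 scale. The genes higher in LPS vs control and the genes lower in LPS vs control numbered 1190 and 1048 without control replicate 1, and without control replicate 2 they were 1233 and 916. Scaling by library totals moved the median log2 fold change of all genes from −0.05 to −0.69 and gave 1417 higher and 5111 lower, so 21.7% of calls were higher in place of 52.6%.

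**Figure D1:**
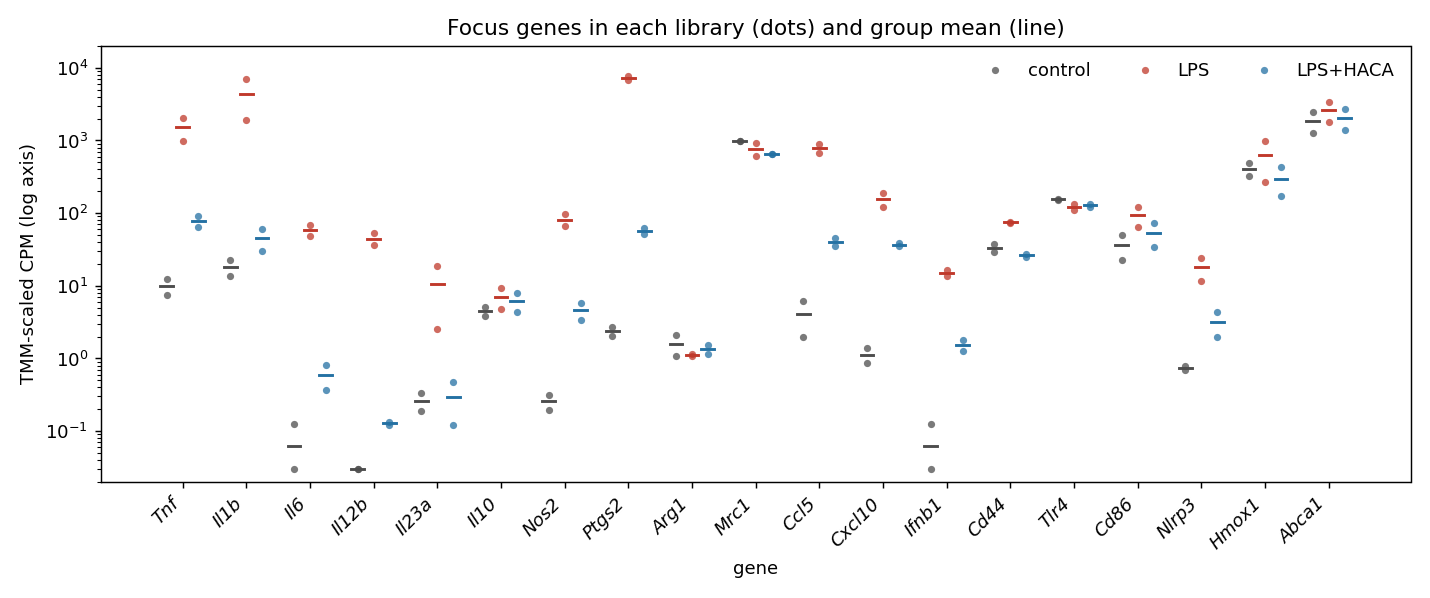
TMM-scaled CPM on a log axis for 19 focus genes in each library (dots, n = 2 per group) with the group mean (line); values under 0.03 CPM are drawn at 0.03. Ptgs2 stands at 2.39 CPM in control, 7305 in LPS and 56.8 in LPS+HACA, while Tlr4 stands at 154, 122 and 129.

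Secreted mediators rose together. All 15 measured cytokine genes were higher (15 adjusted over the list alone, median log2 fold change 6.80), as were 13 of 15 chemokine genes (14 adjusted over the list alone, median 6.42, and 12 with 1 lower under library totals) and 11 of 12 psoriasis-linked myeloid mediators (11 adjusted over the list alone, median 6.59). Their camera adjusted p-values were 3.43e-12, 8.92e-11 and 2.19e-09, and adjusted p = 0.15, 0.12 and 0.15 with an estimated correlation. Il1b, a product of inflammasome-activated cells, rose by 7.90 ± 0.93 (adjusted p = 0.00349) and Il23a, the second subunit of interleukin 23, by 5.30 ± 1.11 (adjusted p = 0.0128). Among chemokine genes, Cxcl9 rose by 8.41 ± 0.53, Ccl5 by 7.58 ± 0.61 and Cxcl10 by 7.10 ± 0.39, and Cxcl3 had 2 counts in control and 444 in LPS (ratio 336, 92.4 to 2782). The interferon gene Ifnb1 had 2 and 307 counts (ratio 232, 63.7 to 1926). Leaving out control replicate 1 or 2 ended the call of Il23a (adjusted p = 0.0994 and 0.0845), and with limma-voom it did not pass on all 6 libraries (adjusted p = 0.13).

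The interferon-stimulated list had 30 of 30 members higher (30 adjusted over the list alone), led by the antiviral genes Gbp5 (6.58 ± 0.29) and Rsad2 (6.23 ± 0.36). NF-kB feedback regulators had 17 of 20 higher (18 adjusted over the list alone), led by the phosphatase gene Dusp2 (5.79 ± 0.51) and Nfkbiz (5.36 ± 0.36). The median log2 fold changes of these lists were 4.21 and 2.73 and the camera adjusted p-values 2.08e-21 and 8.92e-11, with adjusted p = 0.12 and 0.332 with an estimated correlation. Classical activation markers had 16 of 20 higher (20 adjusted over the list alone, median 4.61), among them Edn1, the endothelin 1 gene, with 1 count in control and 655 in LPS (ratio 991, 177 to 39200). The camera adjusted p was 3.43e-12, and adjusted p = 0.12 with an estimated correlation. MHC class I genes had 15 of 16 higher (16 adjusted over the list alone, median 2.41), including H2-Q7 (4.27 ± 0.65) and the proteasome activator gene Psme2 (3.42 ± 0.32). That list's camera adjusted p was 2.43e-09, and adjusted p = 0.15 with an estimated correlation.

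TLR4 signalling parts had 10 of 20 higher and 2 lower (11 and 2 adjusted over the list alone, median 0.87, camera adjusted p = 0.0116, and adjusted p = 0.332 with an estimated correlation). Under library totals 8 were higher and 4 lower, with a median of 0.23. The co-receptor gene Cd14 rose by 3.42 ± 0.35 and the adaptor gene Myd88 by 2.55 ± 0.43, and Tab1 fell by 2.63 on the log2 scale (± 0.29). Tlr4 itself stood at −0.33 ± 0.20 (adjusted p = 0.249). Without LPS replicate 2 the list no longer passed (adjusted p = 0.0739). Cholesterol synthesis genes had 15 of 24 higher (15 adjusted over the list alone, median 1.57, camera adjusted p = 1.03e-05, and adjusted p = 0.395 with an estimated correlation), with the sterol enzyme gene Hsd17b7 up by 3.01 ± 0.40. Under library totals 11 were higher and 1 lower, with a median of 0.96. NRF2 targets had 11 of 20 higher and 1 lower (14 and 1 adjusted over the list alone, median 1.44, camera adjusted p = 0.000489, and adjusted p = 0.47 with an estimated correlation). Under library totals 7 were higher and 2 lower, with a median of 0.77. The cystine transporter gene Slc7a11 rose by 6.11 ± 1.25 (adjusted p = 0.0295) and Gpx1 fell by 1.84 (± 0.37), while Hmox1 stood at 0.61 ± 0.74 (adjusted p = 0.587). Slc7a11 no longer passed without either control or either LPS library (adjusted p = 0.0768 to 0.156), nor Gpx1 without control replicate 1 (adjusted p = 0.0653). The unfolded protein response list had 7 of 20 higher (9 adjusted over the list alone), with a median of 0.57 that turned to −0.07 under library totals, with 6 higher and 2 lower (camera adjusted p = 0.00404, and adjusted p = 0.15 with an estimated correlation). Its largest rise was held by Chac1, which degrades glutathione (7.10 ± 1.09, adjusted p = 0.0627 and 0.0639 without control replicate 1 or 2, and 0.0564 with limma-voom), and the stress pseudokinase gene Trib3 rose by 6.43 ± 0.56.

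The remaining pathway lists did not pass camera in LPS. With fry, lysosome and phagocytosis, glycolysis, and hyaluronan receptors and enzymes passed (fry adjusted p = 0.025, 0.0334 and 0.0411), and the others did not. Of the lists that passed camera, NRF2 targets did not pass fry (fry adjusted p = 0.0722), and the rest did. Alternative activation markers had 4 of 15 higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.477, median 0.55). Under library totals 2 were higher and 4 lower (median −0.14). The lectin gene Clec10a fell by 4.78 (± 0.67) and the scavenger receptor gene Stab1 by 1.05 (± 0.20, adjusted p = 0.0533 without control replicate 1), while Arg1 stood at −0.50 ± 0.53, Mrc1 at −0.36 ± 0.23 and Il10 at 0.64 ± 0.44 (adjusted p = 0.515, 0.283 and 0.309). The costimulatory gene Cd86 stood at 1.37 ± 0.53 (adjusted p = 0.0945). Hyaluronan receptors and enzymes had 7 of 15 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 0.13, and 0.0254 without control replicate 1), against 5 and 2 under library totals (median 0.27). The hyaluronan receptor gene Cd44 rose by 1.16 ± 0.23 (adjusted p = 0.00797), a call lost under library totals (adjusted p = 0.134) and without control replicate 1 (adjusted p = 0.0974). Tnfaip6, whose product modifies hyaluronan, rose by 3.87 ± 0.93 (adjusted p = 0.0168, and 0.0546 without control replicate 2). Glycolysis genes had 3 of 20 higher and 2 lower (3 and 2 adjusted over the list alone, median 0.44, but −0.19 with 3 higher and 5 lower under library totals, camera adjusted p = 0.21), led by Pfkp (3.46 ± 0.33). Oxidative phosphorylation had 3 of 27 higher and 2 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.982); its median was 0.01 and its mean −0.09. Under library totals 1 was higher and 8 lower, with a median of −0.64. Cycs, which encodes cytochrome c, rose by 2.12 ± 0.21. LXR targets had 1 of 14 higher and 2 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.982); their median was 0.28 and their mean −0.39. Under library totals 0 were higher and 4 lower, with a median of −0.33. The lipid carrier gene Apoe fell by 3.13 (± 0.43), and the cholesterol exporter gene Abca1 stood at 0.48 ± 0.47 (adjusted p = 0.485). The phospholipid transfer gene Pltp had 96 counts in control and 1 in LPS (ratio of control to LPS 63.5, 11.1 to 2532, adjusted p = 0.00208).

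Lysosome and phagocytosis genes had 1 of 24 higher and 7 lower (1 and 7 adjusted over the list alone, median −0.36, camera adjusted p = 0.134), and 1 and 14 under library totals (median −1.05). The transcription factor gene Tfec rose by 3.09 ± 0.36, and the lysosomal regulator Tfeb and the protease gene Ctsa fell by 2.46 (± 0.43) and 2.33 (± 0.25). Inflammasome genes had 6 of 14 higher and 3 lower (6 and 5 adjusted over the list alone, median 0.06, but −0.62 with 4 higher and 6 lower under library totals, camera adjusted p = 0.8). The sensor genes Nlrp3 and Nlrp1b went apart, with Nlrp3 up by 4.58 ± 0.55 and Nlrp1b down (−3.04 ± 0.42), and the ATP-gated channel gene P2rx7 fell by 2.67 (± 0.27). MHC class II genes had 1 of 8 higher and 1 lower (1 and 1 adjusted over the list alone, median 0.35, but −0.29 under library totals, camera adjusted p = 0.523). Matrix remodelling genes had 3 of 17 higher and 2 lower (4 and 2 adjusted over the list alone, median 0.06, but −0.58 with 2 higher and 3 lower under library totals, camera adjusted p = 0.38), with the collagenase gene Mmp13 up by 4.71 ± 0.59 and Adam8 down (−2.02 ± 0.32). Cell cycle genes had 0 of 23 higher and 1 lower (0 and 0 adjusted over the list alone, median 0.11, but −0.45 under library totals, camera adjusted p = 0.982), and the 1 called was Tk1, the thymidine kinase gene (−0.88 ± 0.26). Tk1 no longer passed in 5 of the 6 fits that left out a library (adjusted p = 0.0621 to 0.195), the exception being the fit without LPS replicate 2. Within each group the cell cycle genes were higher in replicate 1: 22 of 23 in control, 21 in LPS and 23 in LPS+HACA, with median CPM of 21.6 against 1.72, 20.7 against 1.73 and 33.4 against 2.43.

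Cell type markers moved in both directions. Macrophage markers had 3 of 17 higher and 5 lower (3 and 5 adjusted over the list alone, median −0.53, camera adjusted p = 0.369), with the myeloid factor gene Spi1 up by 1.84 ± 0.22. Under library totals 2 were higher and 11 lower, with a median of −1.20. Dendritic cell markers had 3 of 8 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.70, but 0.01 with 2 higher and 1 lower under library totals, camera adjusted p = 0.369), with the actin-bundling gene Fscn1 up by 4.88 ± 0.57. T and NK cell markers had 1 of 3 higher and 1 lower (1 and 1 adjusted over the list alone, median −0.53, but −1.27 with 0 and 1 under library totals), B and plasma cell markers 0 and 1 of 3 (0 and 3 adjusted over the list alone, median −1.55, and 0 and 3 under library totals), and erythroid and megakaryocyte markers 1 and 0 of 3 (1 and 0 adjusted over the list alone, median 0.43, but −0.25 with 0 called under library totals). Their camera adjusted p-values were 0.97, 0.212 and 0.638. The B cell gene Ighm fell by 1.95 (± 0.36). Of 6 neutrophil markers none passed (median 0.31, but −0.38 under library totals, camera adjusted p = 0.638), the nearest being Camp (2.27 ± 0.88, adjusted p = 0.0939). None of the 4 stromal markers passed either (median −0.63, and −1.18 under library totals, camera adjusted p = 0.98), and Col1a1 stood at −1.19 ± 2.59 (adjusted p = 0.776). All 4 stromal markers were higher in replicate 1 of each group, with median CPM of 14.4 against 0.331 in control, 6.45 against 0.337 in LPS and 13.3 against 0.237 in LPS+HACA. The mast cell and keratinocyte lists had fewer than 3 measured members; Hdc, the histidine decarboxylase gene, rose by 4.83 ± 0.59, and Krt10 stood at −0.99 ± 0.51 (adjusted p = 0.18). Immediate early and heat shock genes had 7 of 11 higher and 2 lower (7 and 2 adjusted over the list alone, median 1.07, but 0.41 with 4 higher and 2 lower under library totals, camera adjusted p = 0.173), with Ier2 up by 2.53 ± 0.40 and Fos down (−2.13 ± 0.26).

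The second comparison asked what the addition of HACA changed in cells given LPS. Ptgs2 fell from 7305 ± 599.9 to 56.8 ± 7.57 CPM (SD, n = 2 per group; log2 fold change −7.01 ± 0.27, SE, adjusted p = 0.000104). Tnf fell from 1522 ± 740.7 to 78.3 ± 18.2 CPM (−4.28 ± 0.43, adjusted p = 0.00328), Nos2 from 80.97 ± 21.5 to 4.61 ± 1.73 CPM (−4.13 ± 0.37, adjusted p = 0.0026), and Il6 from 58.9 ± 14.4 to 0.588 ± 0.316 CPM (−6.64 ± 0.54, adjusted p = 0.00167). All 15 measured cytokine genes and 28 of 30 interferon-stimulated genes fell. Trem2 rose from 7.36 ± 1.15 to 75.8 ± 7.24 CPM (3.36 ± 0.25, adjusted p = 0.00165).

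With HACA 983 genes were higher and 1312 lower than in LPS alone, out of 17113. The groups did not overlap for 57.7% of genes, where chance gives 33.3%. The largest falls were those of Csf2 and Gfi1, which had no count in LPS+HACA and were at least 135 and 99.5-fold lower, and of Areg, with 305 counts in LPS and 1 in LPS+HACA (ratio 464, 82.7 to 18400). Il12b, with 919 counts in LPS and 4 in LPS+HACA, fell by 8.35 (± 0.45). Csf3, which encodes G-CSF, fell by 8.53 (± 1.15) and Il1a by 7.84 (± 0.93), and the plasminogen activator gene Plat had 285 and 3 counts (ratio 145, 49.0 to 705). The largest rises were those of the receptor gene Gpr162 (4.63 ± 0.65), Zfyve28 (4.44 ± 0.30), Bmf, a promoter of apoptosis (3.67 ± 0.26), Zfp395 (3.66 ± 0.40), Otulinl (3.51 ± 0.64), Trem2, Edaradd (3.17 ± 0.40) and Nol4l (3.16 ± 0.31). Zfyve28 lies on chromosome 5 (34194893 to 34288449) and Trem2 on chromosome 17 (48346401 to 48354147). With DESeq2 the calls of Csf2 and Gfi1 did not pass (adjusted p = 0.131 and 0.154). The calls of Areg, Csf3 and Il1a were lost without LPS+HACA replicate 1 (adjusted p = 0.134, 0.0787 and 0.077) and without LPS+HACA replicate 2 (adjusted p = 0.113, 0.0653 and 0.0625). With limma-voom on all 6 libraries Areg and Csf3 did not pass either (adjusted p = 0.0869 and 0.11). The genes higher in LPS+HACA vs LPS and the genes lower in LPS+HACA vs LPS numbered 344 and 652 without control replicate 1, 317 and 637 without control replicate 2, 1617 and 1793 without LPS replicate 1, 152 and 216 without LPS+HACA replicate 1, and 292 and 377 without LPS+HACA replicate 2. Scaling by library totals moved the median log2 fold change from 0.06 to 0.70 and gave 3501 higher and 522 lower, so 87% of calls were higher in place of 42.8%.

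**Figure D2:**
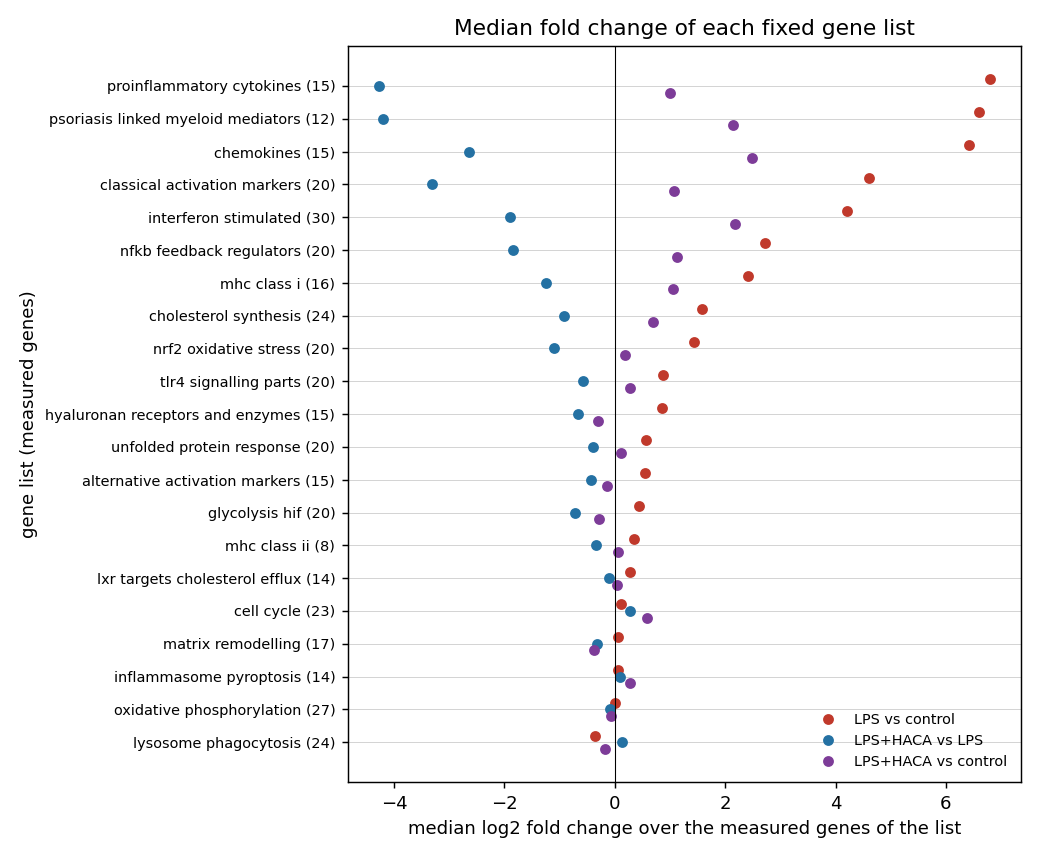
Median log2 fold change over the measured genes of each of the 21 pathway lists in the 3 contrasts, with the number of measured genes in brackets. The cytokine list stands at 6.80 in LPS against control and −4.28 in LPS+HACA against LPS, under library totals the medians of 9 of these lists in the first contrast and 7 in the second change sign, as given in the text for each (TLR4 list in LPS+HACA against LPS −0.57 against 0.08).

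The secreted mediators fell with HACA. The cytokine list had 15 of 15 lower (15 adjusted over the list alone, median −4.28), chemokines 11 of 15 (13 adjusted over the list alone, median −2.64) and psoriasis-linked mediators 11 of 12 (11 adjusted over the list alone, median −4.21). Camera gave adjusted p-values of 4.73e-15, 1.68e-11 and 5.02e-11 for them, with adjusted p = 0.141 for each with an estimated correlation. Il1b fell by 6.59 (± 0.88) and Il23a by 5.13 (± 1.09). The chemokine gene Ccl4 fell by 5.34 (± 0.31), Ccl5 by 4.27 (± 0.52) and Cxcl10 by 2.07 (± 0.30), and Ifnb1 fell by 3.26 (± 0.45). Il1b no longer passed without LPS+HACA replicate 1 or 2 (adjusted p = 0.077 and 0.0653), nor did Il23a in any of the 6 fits except the one without LPS replicate 1 (adjusted p = 0.0649 to 0.158). With limma-voom on all 6 libraries Il23a did not pass (adjusted p = 0.175). Ccl5 did not pass without LPS replicate 2 (adjusted p = 0.0563), nor Cxcl10 without LPS+HACA replicate 1 (adjusted p = 0.0504).

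Interferon-stimulated genes had 28 of 30 lower (30 adjusted over the list alone, median −1.90), among them Isg15, a ubiquitin-like modifier (−2.78 ± 0.22), and Oasl1 (−2.70 ± 0.32). NF-kB feedback regulators had 13 of 20 lower (13 adjusted over the list alone, median −1.85), with Dusp2 at −3.61 ± 0.46 and the cytokine-signalling suppressor Socs3 at −3.08 ± 0.28. Their camera adjusted p-values were 1.05e-18 and 2.6e-08, and adjusted p = 0.141 and 0.284 with an estimated correlation. Classical activation markers had 13 of 20 lower (19 adjusted over the list alone, median −3.31, camera adjusted p = 5.96e-13, and adjusted p = 0.141 with an estimated correlation), with Edn1 at −6.36 ± 0.67. MHC class I genes had 10 of 16 lower (14 adjusted over the list alone, median −1.24, camera adjusted p = 6.74e-08, and adjusted p = 0.141 with an estimated correlation). Under library totals 2 of the 16 were lower and the median was −0.58, and 20 of the 30 interferon-stimulated genes were lower with a median of −1.26. The NF-kB feedback list then had 10 lower and 1 higher, with a median of −1.17. The peptide transporter gene Tap1 fell by 1.90 (± 0.26, adjusted p = 0.00642, and 0.0602 without LPS+HACA replicate 1).

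TLR4 signalling parts had 5 of 20 lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0164, and adjusted p = 0.284 with an estimated correlation), with a median of −0.57 that turned to 0.08 under library totals, with 1 lower and 2 higher. Cd14 fell by 2.57 (± 0.34) and Tab1 rose by 2.02 ± 0.29, while Tlr4 stood at 0.07 ± 0.20 (adjusted p = 0.845). The list did not pass without LPS replicate 2 (adjusted p = 0.141). Cholesterol synthesis had 6 of 24 lower (7 adjusted over the list alone, median −0.92, camera adjusted p = 0.000196, and adjusted p = 0.407 with an estimated correlation). Under library totals 1 was lower and 1 higher, with a median of −0.30. Hsd17b7 fell by 2.19 (± 0.39), a call lost without LPS+HACA replicate 2 (adjusted p = 0.0653). NRF2 targets had 3 of 20 lower (6 adjusted over the list alone, median −1.10, camera adjusted p = 8.68e-05, and adjusted p = 0.407 with an estimated correlation). Under library totals 1 was lower and 1 higher, with a median of −0.42. The superoxide dismutase gene Sod2 fell by 1.71 (± 0.29, adjusted p = 0.0122, and 0.0915 without LPS+HACA replicate 1), and Hmox1 stood at −1.06 ± 0.75 (adjusted p = 0.399). Hyaluronan receptors and enzymes had 4 of 15 lower (5 adjusted over the list alone, median −0.67, camera adjusted p = 0.0248, and adjusted p = 0.195 with an estimated correlation). With fry the hyaluronan list did not pass (fry adjusted p = 0.059). Nor did the TLR4, cholesterol synthesis and NRF2 lists (fry adjusted p = 0.117, 0.14 and 0.117). The other lists that passed camera in LPS+HACA against LPS also passed fry. Cd44 fell from 74.5 ± 0.558 to 26.3 ± 1.59 CPM (−1.50 ± 0.23, adjusted p = 0.00913), a call lost without LPS+HACA replicate 1 or 2 (adjusted p = 0.0831 and 0.0527). The hyaluronan list itself did not pass without LPS replicate 1 (adjusted p = 0.149), and under library totals it had 3 lower and a median of −0.03.

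Glycolysis genes had 4 of 20 lower (6 adjusted over the list alone, median −0.72, camera adjusted p = 0.00949, and adjusted p = 0.195 with an estimated correlation), with Slc2a6, a hexose transporter gene, at −1.54 ± 0.25. Under library totals 2 were lower and 1 higher, with a median of −0.05. The unfolded protein response list had 3 of 20 lower (3 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.141 with an estimated correlation), with a median of −0.39 that was 0.26 under library totals, with 0 called. The chaperone gene Hspa5 fell by 1.46 (± 0.28) and Atf3 by 1.45 (± 0.27), both lost under library totals (adjusted p = 0.0621 and 0.0553), without LPS+HACA replicate 1 (adjusted p = 0.13 and 0.119) and without LPS+HACA replicate 2 (adjusted p = 0.0767 and 0.0667). Matrix remodelling had 3 of 17 lower (3 adjusted over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.203 with an estimated correlation), with a median of −0.32 that was 0.35 under library totals, with 3 lower and 2 higher, and it did not pass without LPS replicate 1 (adjusted p = 0.0525). Serpinb2 had 153 counts in LPS and 2 in LPS+HACA (ratio 116, 31.7 to 970.3). Alternative activation markers had 3 of 15 lower (3 adjusted over the list alone, median −0.43, but 0.26 with 2 lower and 1 higher under library totals, camera adjusted p = 0.0608, and 0.0314 without LPS+HACA replicate 2). Arg1 stood at 0.27 ± 0.54, Mrc1 at −0.24 ± 0.23, Il10 at −0.18 ± 0.43 and Cd86 at −0.81 ± 0.52 (adjusted p = 0.772, 0.531, 0.817 and 0.34).

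Lysosome and phagocytosis genes had 4 of 24 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.45), with Ctsa up by 1.62 ± 0.25. Under library totals 9 were higher and 1 lower, with a median of 0.80. Inflammasome genes had 2 of 14 higher and 2 lower (2 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.871), against 6 and 1 under library totals (median 0.75). P2rx7 rose by 1.92 ± 0.26, and Nlrp3 fell from 17.9 ± 8.60 to 3.17 ± 1.64 CPM (adjusted p = 0.0169, and 0.0979 without LPS+HACA replicate 1). Oxidative phosphorylation had 1 of 27 lower (1 adjusted over the list alone, median −0.09, mean 0.05, and median 0.54 with 4 higher and 1 lower under library totals, camera adjusted p = 0.77). LXR targets had 1 of 14 higher (1 adjusted over the list alone, median −0.11, mean 0.20, and median 0.52 with 3 higher under library totals, camera adjusted p = 0.77), and Abca1 stood at −0.36 ± 0.47 (adjusted p = 0.648). The higher one was Pltp, with 1 count in LPS and 36 in LPS+HACA (ratio 23.7, 3.98 to 959.7, adjusted p = 0.0205), a call lost without control replicate 1 or 2 (adjusted p = 0.0544 and 0.0587) and without LPS+HACA replicate 1 or 2 (adjusted p = 0.0582 and 0.0839). MHC class II had 1 of 8 lower (1 adjusted over the list alone, median −0.34, but 0.31 with 1 higher and 0 lower under library totals, camera adjusted p = 0.502). Cell cycle genes had 1 of 23 higher (1 adjusted over the list alone, median 0.28, and 0.88 under library totals, camera adjusted p = 0.596). The list passed only without LPS+HACA replicate 2, which held a median of 2.43 CPM of these genes against 33.4 in replicate 1. That fit sets unlike replicate numbers against each other.

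Macrophage markers had 1 of 17 higher, Trem2, and 1 lower, Spi1 (2 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.764). Under library totals 6 were higher and 0 lower, with a median of 0.93. Spi1 fell by 1.17 (± 0.21, adjusted p = 0.0139), a call lost under library totals (adjusted p = 0.0743) and without LPS+HACA replicate 1 or 2 (adjusted p = 0.115 and 0.0701). Dendritic cell markers had 2 of 8 lower (1 higher and 5 lower adjusted over the list alone, median −1.78, and −1.12 with 1 higher and 2 lower under library totals, camera adjusted p = 0.0585), with Fscn1 at −3.81 ± 0.53. Of 3 markers each, B and plasma cells had 1 higher (1 adjusted over the list alone, median 1.10, and 1.78 under library totals), erythroid and megakaryocyte cells 1 lower (2 adjusted over the list alone, median −1.20, and −0.53 with 0 called under library totals), and T and NK cells 0 (1 higher and 1 lower adjusted over the list alone, median 0.01, −0.04 with DESeq2 size factors, and 0.72 with 1 higher under library totals). Their camera adjusted p-values were 0.229, 0.375 and 0.925. Ighm rose by 1.77 ± 0.36, a call lost without control replicate 1, control replicate 2 and LPS+HACA replicate 1 (adjusted p = 0.0554, 0.0587 and 0.134). No neutrophil or stromal marker passed (medians −0.84 and 0.49, and −0.15 and 1.06 under library totals, camera adjusted p = 0.375 and 0.925, the stromal direction in camera being down); Camp stood at −1.98 ± 0.87 (adjusted p = 0.173) and Col1a1 at 1.18 ± 2.59 (adjusted p = 0.805). Hdc of the mast cell list fell by 3.51 (± 0.54), and Krt10 of the keratinocyte list stood at 1.20 ± 0.51 (adjusted p = 0.154). Immediate early and heat shock genes had 1 of 11 higher and 4 lower (2 and 7 adjusted over the list alone, median −1.31, but −0.60 with 2 higher and 2 lower under library totals, camera adjusted p = 0.0364, and adjusted p = 0.65 with an estimated correlation). Junb fell by 1.89 (± 0.29, adjusted p = 0.00845, and 0.0632 without LPS+HACA replicate 1).

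Set side by side, the 2 comparisons moved genes in opposite directions. Of the genes that LPS raised, 1270 (46.8%) were lower with HACA, and of those that LPS lowered, 964 (39.5%) were higher with HACA. Il6, Il12b, Ptgs2 and Tnf were in the first set and Trem2, Bmf, P2rx7 and Zfyve28 in the second. Another 61 genes were called in LPS+HACA against LPS but not in LPS against control. Among them was the inhibitor of DNA binding gene Id3, chosen after its values were seen. It fell from 79.05 ± 48.6 to 5.22 ± 1.71 CPM (29.7 ± 17.1 in control), a call lost without LPS+HACA replicate 1 or 2 (log2 fold change −3.59 and −4.305, against −3.92 with all libraries). A gene not called in LPS against control can still have changed there, and Id3 stood at 1.41 (edgeR adjusted p = 0.103). No gene was called in the same direction in both by edgeR, DESeq2 or limma-voom, and at an unadjusted p under 0.05 edgeR gave 0 higher and 1 lower; library totals gave 1 lower gene. The same LPS libraries stand in both comparisons, which gives opposed calls without any effect of HACA: 100 simulated groups with no effect gave at most 6 and 5 opposed genes, and independent lists of these sizes would share 208 and 140.3. Across genes, which are not independent replicates, the log2 fold changes correlated at r = −0.916 (simulated −0.213), with a covariance of −1.88 against a simulated −0.25, a difference of −1.62. With a different LPS library in each contrast, the correlation of log2 fold changes of LPS vs control with LPS+HACA vs LPS was −0.641 or −0.678. These 2 values used differences of log2 CPM in place of fitted fold changes, and LPS libraries of different replicate number. Their distance from −0.916 therefore does not measure the part due to shared libraries. With 2 LPS libraries the shared group could not be split with 2 in each part, so part of the excess over the simulated values can come from the shared libraries. The genes LPS raised and HACA lowered and the genes LPS lowered and HACA raised numbered 608 and 333 without control replicate 1, 591 and 303 without control replicate 2, 1693 and 1536 without LPS replicate 1, 214 and 152 without LPS+HACA replicate 1, and 376 and 290 without LPS+HACA replicate 2. Under library totals the overlaps were 503 and 3245, against at most 4 and 5 in 100 simulations with that scaling.

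**Figure D3:**
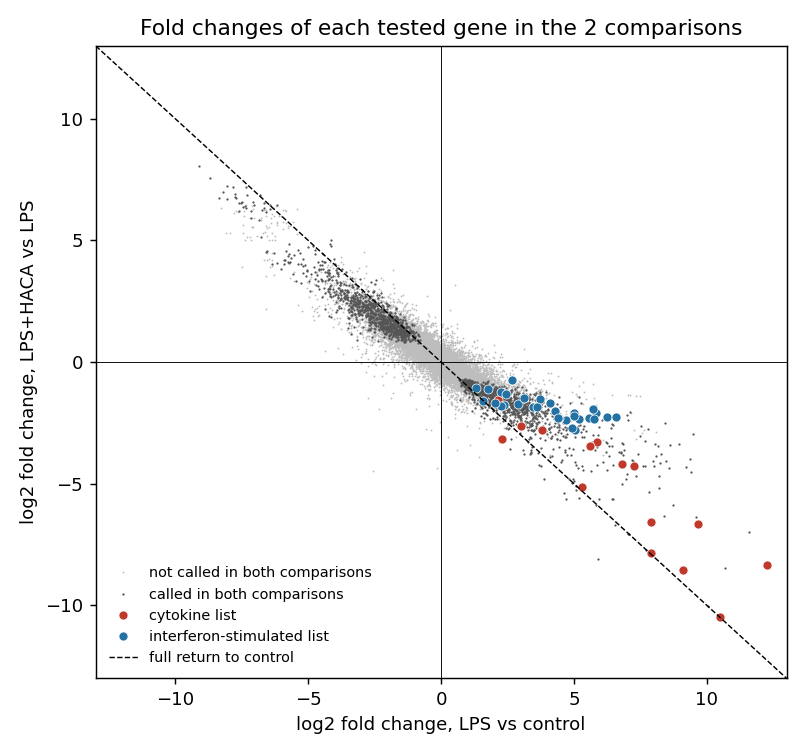
Log2 fold change of each of the 17113 tested genes in LPS against control (horizontal axis) and in LPS+HACA against LPS (vertical axis), with genes called in both in dark grey, cytokine genes in red and interferon-stimulated genes in blue. Points on the dashed line would be back at the control level; the correlation across genes is −0.916, and simulations with no effect of HACA, which share the LPS libraries, give −0.213.

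The third comparison asked how far cells given LPS and HACA stood from control cells. Ptgs2 remained above control at 56.8 ± 7.57 against 2.39 ± 0.454 CPM (SD, n = 2 per group; log2 fold change 4.57 ± 0.25, SE, adjusted p = 0.00163). Of the fixed lists, the interferon-stimulated one held the most calls, with 18 of 30 higher (25 adjusted over the list alone, median 2.17), among them Gbp5 (4.33 ± 0.26), Rsad2 (3.96 ± 0.33) and Isg15 (2.25 ± 0.21). Of the cytokine genes 3 of 15 were higher (6 adjusted over the list alone), including Tnf at 78.3 ± 18.2 against 9.88 ± 3.42 CPM (2.99 ± 0.42, adjusted p = 0.0222), while Il1b stood at 1.31 ± 0.71 (adjusted p = 0.598). The macrophage lipid gene Apoe remained below control (−2.58 ± 0.41, adjusted p = 0.033). The genes given here were chosen for the other comparisons, not by a rule for this one.

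In all 153 genes were higher and 44 lower than in control, and the groups did not overlap for 46.5% of genes, where chance gives 33.3%. Of these 197 genes, 196 were called the same way in LPS against control. The other was Mex3b, an RNA-binding protein gene chosen after its values were seen (4.14 ± 0.45 CPM against 19.5 ± 1.19 in control and 14.3 ± 6.59 in LPS). The same control libraries stand in both comparisons, which favours calls in the same direction, and no simulation was run for this pair. The 2715 genes that LPS raised had a median log2 fold change of 1.77 in LPS and 0.63 in LPS+HACA against control, and 94.2% of them lay between control and LPS. For the 2442 that LPS lowered the medians were −2.05 and −0.56, and 93.0% lay between. Chemokines had 5 of 15 higher (8 adjusted over the list alone), with Cxcl10 at 5.03 ± 0.36, Cxcl9 at 5.92 ± 0.50 and Ccl5 at 3.31 ± 0.51. NF-kB feedback regulators had 3 of 20 (15 adjusted over the list alone, and 5 under library totals), MHC class I genes 2 of 16 (11 adjusted over the list alone), classical activation markers 5 of 20 (6 adjusted over the list alone) and psoriasis-linked mediators 2 of 12 (6 adjusted over the list alone). Camera adjusted p-values were 1.82e-30 for the interferon-stimulated list, 1.54e-10 for chemokines, 1.17e-13 for NF-kB feedback, 1.89e-09 for MHC class I, 4.11e-09 for classical markers, 5.63e-06 for psoriasis-linked mediators and 3.15e-05 for cytokines. In the same order, adjusted p = 0.11, 0.11, 0.348, 0.185, 0.185, 0.327 and 0.385 with an estimated correlation. With fry, the interferon-stimulated, chemokine, MHC class I and classical lists passed. NF-kB feedback, psoriasis-linked mediators and cytokines did not (fry adjusted p = 0.092, 0.098 and 0.202). With genes at 0 in a group set to their bound, the cytokine median was 0.59 and the psoriasis-linked median 0.97, against 2.15 as fitted. Cholesterol synthesis (median 0.70; 0 of 24 higher, 3 adjusted over the list alone, camera adjusted p = 3.35e-05) and lysosome genes (median −0.17; 0 of 24 called, camera adjusted p = 0.0488) also passed camera, with adjusted p = 0.431 and 0.366 with an estimated correlation. Neither passed fry (fry adjusted p = 0.242 for each). Cholesterol synthesis did not pass without LPS+HACA replicate 1, and lysosome genes did not without control replicate 2, either LPS library or LPS+HACA replicate 1. Some lists passed only with a library left out. Cell cycle genes did so, upward, without control replicate 1 or LPS+HACA replicate 2, and NRF2 targets, upward, without LPS+HACA replicate 1. Alternative activation markers did so, downward, without control replicate 1 or LPS+HACA replicate 2. The median CPM of the cell cycle genes was 21.6 and 1.72 in control replicates 1 and 2, and 33.4 and 2.43 in LPS+HACA. Leaving out either library therefore sets unlike replicate numbers against each other, and the upward result of the cell cycle list cannot be read as an effect of treatment.

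With edgeR, 0 higher and 0 lower genes remained called without control replicate 1 (718 and 428 at an unadjusted p under 0.05) and 2 and 0 without control replicate 2 (849 and 358 unadjusted), so without control replicate 1 no gene named for it passed (adjusted p = 0.0768 for Ptgs2 and Gbp5, 0.255 for Tnf and 0.237 for Apoe), and without control replicate 2 only Ptgs2 and Gbp5 of the genes given here as called did. Leaving out a control library leaves 1 in that group. Without control replicate 1 the errors of Ptgs2, Gbp5, Tnf and Apoe grew and their direction held (4.37 ± 0.38, 4.09 ± 0.36, 2.66 ± 0.53 and −2.83 ± 0.50). Ccl5 and Cxcl9 moved further, to 2.695 and 5.308, from 3.313 and 5.919 with all libraries. They stood at 4.379 and 6.911 without control replicate 2. Rsad2 and Isg15 moved less without control replicate 1, to 3.916 and 2.183 from 3.963 and 2.246. The genes that did not pass without control replicate 2 were Tnf, Apoe, Cxcl9, Cxcl10, Ccl5, Rsad2, Isg15 and Mex3b (adjusted p = 0.159, 0.301, 0.0823, 0.0906, 0.0823, 0.116, 0.139 and 0.28). Ccl5 passed in none of the 6 fits that left out a library (adjusted p = 0.128 and 0.138 without LPS replicate 1 and 2). Apoe did not pass without LPS+HACA replicate 1 (adjusted p = 0.125), Tnf without LPS+HACA replicate 2 (adjusted p = 0.0781), or Mex3b without either (adjusted p = 0.184 and 0.165). The genes higher in LPS+HACA vs control and the genes lower in LPS+HACA vs control numbered 415 and 181 without LPS replicate 1, 420 and 186 without LPS replicate 2, 59 and 3 without LPS+HACA replicate 1, and 44 and 1 without LPS+HACA replicate 2. DESeq2, run on all 6 libraries, gave 466 and 200, and limma-voom 139 and 74.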

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

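This value was counted only after the data were seen. The transcripts that matched no gene of the annotation were used in no comparison. Of these 1123 transcripts, 53 had at least 20 counts in both LPS libraries, and 10 of those stood at least 4-fold above both control libraries. All 10 were lower in both LPS+HACA libraries than in both LPS libraries, and 2 transcripts with at least 20 counts in both control libraries were at least 4-fold lower in both LPS libraries. No gene was assigned to them, and no explanation was tested.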

How the results depend on the processing

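The settings with protein-coding genes only, with genes of 1 annotated transcript only and with transcripts tested one by one were chosen after seeing the data. Single genes were compared under DESeq2 size factors, library totals, DESeq2, limma-voom, the replicate block and each library left out. The other settings were not applied to single genes, and a setting that gave a gene no adjusted p was skipped for it. Of 199 gene results for 119 genes, 86 kept their direction and their side of the threshold under every setting so applied, and 12 reversed under at least 1.

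Scaling by library totals gave, for genes higher in LPS vs control, 1417, for genes lower in LPS vs control 5111, for genes higher in LPS+HACA vs LPS 3501, for genes lower in LPS+HACA vs LPS 522 and for genes lower in LPS+HACA vs control 24. It gave 503 genes LPS raised and HACA lowered and 3245 genes LPS lowered and HACA raised. Library totals include the counts of the genes that LPS raised. With no filter there were 1845 genes higher in LPS+HACA vs LPS, 661 genes higher in LPS+HACA vs control, 250 genes lower in LPS+HACA vs control and 1715 genes LPS lowered and HACA raised, and the correlation of log2 fold changes of LPS vs control with LPS+HACA vs LPS was −0.735. With the replicate number as a block these were 1955 genes higher in LPS+HACA vs LPS, 2356 lower, 628 and 307 against control, and 2185 and 1840 in the overlaps. The block also moved list members called: NRF2 targets in LPS+HACA against LPS from 3 to 13 of 20 lower, and against control cholesterol synthesis from 0 to 11 of 24 and NF-kB feedback from 3 to 12 of 20 higher. In LPS against control, cell cycle genes went from 0 higher and 1 lower to 4 higher and 4 lower of 23. The deviations of same-numbered libraries from their group means correlated at 0.308, 0.509 and 0.498 between groups. On the second axis of a principal component analysis of log2 CPM (18.4% of the variance), replicate 1 stood at 17.1 in control, 59.7 in LPS and 43.4 in LPS+HACA. Replicate 2 stood at −34.7, −50.1 and −35.4. Both results show a difference shared by number in each group, and its source was not tested. The labels give the number no meaning and each group has 2 libraries, so the fits without the block stand as planned. Those fits keep any such shared effect in their error, and the simulations with no effect of HACA leave it out. The causes of the shifts under these settings were not tested.

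Fewer genes were tested with 1 annotated transcript only: 812 genes higher in LPS vs control, 774 genes lower in LPS vs control, 319 genes higher in LPS+HACA vs LPS, 314 genes lower in LPS+HACA vs LPS, 43 genes higher in LPS+HACA vs control, 10 genes lower in LPS+HACA vs control, 302 genes LPS raised and HACA lowered and 309 genes LPS lowered and HACA raised. Protein-coding genes only gave 28 genes lower in LPS+HACA vs control. With only the 4 libraries compared there were 252 genes higher in LPS+HACA vs LPS, 509 genes lower in LPS+HACA vs LPS, 324 genes higher in LPS+HACA vs control and 159 genes lower in LPS+HACA vs control. Of genes higher in LPS+HACA vs control and genes lower in LPS+HACA vs control, DESeq2 gave 466 and 200, limma-voom 74 lower, limma on log2(FPKM + 1) 77 higher, and transcripts one by one 249 and 87; the cause was not tested. Separated libraries without a test gave 4083 genes LPS raised and HACA lowered. With 1 LPS library in each contrast and differences of log2 CPM in place of fitted fold changes, the correlation of log2 fold changes of LPS vs control with LPS+HACA vs LPS was −0.641 or −0.678. With the inter-gene correlation estimated by camera, gene lists changed in LPS vs control numbered 0 (6 at an unadjusted p under 0.05, 13 with fry) and gene lists changed in LPS+HACA vs LPS 0 (7 and 10).

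Leaving out each library in turn assumes that the lone library varies like the other groups. The genes higher in LPS vs control ranged from 1190 to 3024 and genes lower in LPS vs control from 916 to 2817 (lowest without control replicate 1 and 2, highest without LPS replicate 1). The genes higher in LPS+HACA vs LPS ranged from 152 to 1617 and genes lower in LPS+HACA vs LPS from 216 to 1793 (lowest without LPS+HACA replicate 1, highest without LPS replicate 1). The genes higher in LPS+HACA vs control ranged from 0 to 420 and genes lower in LPS+HACA vs control from 0 to 186 (edgeR; 718 and 428 at an unadjusted p under 0.05 without control replicate 1). The genes LPS raised and HACA lowered ranged from 214 to 1693 and genes LPS lowered and HACA raised from 152 to 1536. The correlation of log2 fold changes of LPS vs control with LPS+HACA vs LPS ranged from −0.93 to −0.776, gene lists changed in LPS vs control from 10 to 12 and gene lists changed in LPS+HACA vs LPS from 12 to 16.

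Every reversed gene value had missed the threshold. Under library totals, the log2 fold change of Mrc1 in LPS+HACA vs LPS was 0.38, of Il10 0.44, of Abca1 0.32 and of Top2a, chosen after its values were seen, 0.27, and in LPS vs control that of Hmox1 was −0.11 and of Abca1 −0.20. Without 1 library, LPS vs control ranged from −0.058 to 1.06 for Abca1, −0.93 to 0.075 for Arg1, −4.69 to 3.23 for Col1a1, −0.61 to 1.27 for Hmox1, and the log2 fold change of Top2a in LPS vs control from −2.25 to 4.13. LPS+HACA vs LPS ranged from −0.92 to 0.18 for Abca1, −1.88 to 0.16 for Hmox1, −0.65 to 0.36 for Il10, −0.51 to 0.10 for Mrc1, and −3.69 to 3.42 for Top2a, the log2 fold change of Tlr4 in LPS+HACA vs LPS from −0.046 to 0.20, and the log2 fold change of Col1a1 in LPS+HACA vs LPS from −3.40 to 4.68. Top2a is in the cell cycle list and Col1a1 in the stromal list, and the medians of both lists were higher in replicate 1 of each group. Leaving out 1 library therefore changes the balance of replicate numbers for these 2 genes. The cause was not tested for the other genes. Depth limits the genes near 0 counts, whose folds are given as bounds or count ratios.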

Other observations

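The tests of a mixture, of scaling, of depth, of stromal cells and of the share of the LPS rise were chosen only after the results were seen.

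Genes changed by LPS mostly lay between control and LPS in the LPS+HACA libraries. A mixture of RNA from fully LPS-treated and untreated cells would leave the same share of the rise in every gene list. The median share left was 19.5% for 30 interferon-stimulated genes and 0.892% for 15 cytokine genes, a ratio of 21.8 (42.6 in the first library and 13 in the second). These shares differed, which a mixture alone would not give, but the lists were picked because of this difference in the same libraries. The ratio is therefore no independent test of a mixture. Under library totals the smaller opposed overlap was 503. At most 5 opposed genes arose in 100 simulations with no effect of HACA under that scaling. The simulations gave the LPS and LPS+HACA libraries the same composition, so no scaling offset between these groups could arise in them. They therefore cannot exclude scaling as part of the cause. Opposed genes in both directions were found under both scalings, 1270 and 964 with TMM factors and 503 and 3245 with library totals. A direct effect of HACA on the cells, a lower effective amount of LPS and a mixture as part of the cause stay open. These data hold no test between them.

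A hypothesis from this pattern is that interferon-stimulated genes keep more of their LPS rise than cytokine genes. The medians differed by 18.6 percentage points (two-sided permutation of genes, p = 2e-05). Both lists were picked because of this difference in the same libraries, so the permutation is no test of the hypothesis, which stays open. Across all 2715 genes raised by LPS the median share left was 20.2%, and lists matched to the interferon-stimulated one had 16.1%, so of these 2 lists the cytokine one, at 0.892% against 9.83% in its matched lists, lay further from its matched lists. Against 10000 lists matched for the size of the LPS rise, the cytokine list stood at percentile 0.015 and psoriasis-linked mediators at 0.065. Immediate early and heat shock genes stood at 0.775 (7 genes) and interferon-stimulated genes at 93.0. The matched lists were drawn gene by gene, so they lack the shared regulation that members of a list can have. The percentiles are therefore descriptive and are no p-values. The unfolded protein response stood at 99.4 (7 genes, 38.0% of the rise left) and the inflammasome list at 99.8 (6 genes, 40.6% left). For the unfolded protein response the share was 15.4% in the first LPS+HACA library and 53.3% in the second, against a median of 17.3% over both for its matched lists.

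Cell cycle genes were higher in the replicate 1 library of each group. A difference in depth is argued against, since total counts differed by at most 1.23 times within a group and the deeper number differed between groups. The median ratio of replicate 1 to replicate 2 over the cell cycle genes was 4.89 to 5.93. Dividing stromal cells in the replicate 1 libraries cannot be told apart from other causes, because the highest stromal marker stood at 0.769 to 1.1 times the median CPM of the cell cycle genes and only 4 of 13 listed markers were measured. Col1a1 stood at 10.2 ± 13.8 CPM in control (SD, n = 2). The design names no biological difference between the replicate numbers, and no biological explanation was tested.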
